A study of Mus musculus with 36 samples.

How the data were processed

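The data are RNA-seq libraries from the whole hearts of 36 mice in 6 groups of 6, with control and cSirt4-Tg genotypes, sham surgery or TAC, and MitoQ or vehicle after TAC. Per the labels, RNA was isolated with the RNeasy Fibrous Tissue kit and libraries were made with the NEB Ultra II Directional kit. Per the submitters' processing notes, reads were trimmed with Trim Galore and aligned with STAR to mm39; the versions, the read counter and the normalizing tool are not given in the sources used here. The deposited table holds 1 signal per gene and library, a normalized read count. Each value was checked to be a whole number of reads times 1 step per library (100% of the values within 0.01 read), so the reads were recovered and the table holds gene counts divided by 1 size factor per library. The recovered totals were 14.8 to 60.0 M reads, which is the depth of each library among the listed genes. All columns were matched to a sample by name. Coordinates are those of the deposited table, and only gene types were taken from another annotation.

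Groups were taken from the labels. Sex-linked genes were alike in all libraries, with Y-linked genes on and Xist at most 7.12. Of the 25626 listed genes, the 16275 with a value of at least 10 in at least 6 libraries were tested. Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3 (a linear model with 1 mean per group over all 36 libraries, 30 residual degrees of freedom, moderated with a trend and robustly). The 7 comparisons of 2 groups and the 2 interactions were contrasts of that fit, tested two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A library shows the direction of a difference when it lies on that side of the mean of the other group. Sirt4 was tested with an exact permutation test on its log2 values, two-sided, adjusted over 3 tests.

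The contrasts, the filter, the tests, 35 gene lists with 708 members and the rule for naming genes were fixed before the data were examined. The rule takes Sirt4, up to 8 higher and 8 lower called genes per comparison with the largest differences among those with a mean of at least 100 and every library on the same side, up to 3 called genes with the smallest adjusted p per called list, and for the interactions the 5 with the smallest p. Genes it takes may be left out. Genes named as called in a comparison of 2 groups kept the call in every fit that left out 1 library of it, except where this is stated, and genes named only for following the label in 3 treatments were not all examined in this way. List tests used camera with a preset correlation of 0.01 and, beside it, with an estimated correlation, adjusted over the 35 lists of a contrast. Called members were counted over all genes tested and adjusted over the list alone.

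The opposition of MitoQ and TAC was measured as a count of opposite calls and as the covariance of log2 differences, beside simulated draws without effects and splits of the TAC libraries into 3 and 3. The steps were tested on simulated data. These gave all groups the means and the spread of Con-Sham, apart from the planted changes, with independent genes and no library that stands apart. The rates below may therefore be too favourable for the vehicle TAC groups, whose libraries were less alike, and for lists of correlated genes. Limma recovered 62.7% of planted 1.5-fold, 82.1% of 2-fold and 97.0% of 4-fold changes with 10 false calls, camera called the shifted list and 1 other of 35, and the covariance difference was -0.00108 with no effect and -0.121 where -0.125 was planted.

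Alternatives were other pseudocounts (0.5 and 10), no filter or a minimum of 50, TMM factors, the same total of genes outside the mitochondrial genome, median-centred values, array weights, the replicate number as a block, the class of the name number as a covariate, only the libraries compared, only the libraries named 7 to 14, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Leaving out 4 doubted libraries (Tg-TAC 6, Tg-TAC 4, Con-TAC-MQ 5 and Con-Sham 2) and a permutation test of list means were added after the data were seen. Replicate numbers were checked for pairing: libraries with the same number were not more alike than others (r of paired differences from -0.483 to 0.311), so the main model has no block. Within the groups no 2 libraries were copies of each other (90 pairs, r from 0.874 to 0.990), and pairs across groups were not compared. Exon-level, isoform and variant information is not analysed here, since the deposited table holds gene values alone. In the search for libraries that stand apart from their group, 1 gene is counted and not reported here.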

Results

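RNA from the whole hearts of 36 male mice was sequenced in 6 groups of 6. Control mice (Con) and mice labelled cSirt4-Tg (Tg), named after Sirt4, a mitochondrial sirtuin, had sham surgery or transverse aortic constriction (TAC), which narrows the aorta and loads the left ventricle. The TAC mice received vehicle or MitoQ (MQ), an antioxidant that accumulates in mitochondria. The 6 groups were Con-Sham, Tg-Sham, Con-TAC, Tg-TAC, Con-TAC-MQ and Tg-TAC-MQ, and the stated purpose was to find pathways by which mitochondrial reactive oxygen species could aggravate cardiomyopathy in cSirt4-Tg mice. The libraries held 14.8 to 60.0 M assigned reads, with a median of 28.4 M. Values are normalized read counts with SD and n = 6 per group, and log2 differences carry their SE. Mitochondrially encoded genes took 17.7% to 25.5% of the reads in Con-Sham and 13.1% to 19.6% in Tg-TAC. Rn18s-rs5, a ribosomal RNA locus, took 3.37% to 11.01% of the reads in the sham libraries, 1.55% to 11.8% in the vehicle TAC libraries and 0.591% to 1.39% in the MitoQ libraries. The library names carry a number whose meaning is not given in the sources used here. It was 20 or 21 in all MitoQ libraries and in Con-TAC 6, and 7 to 14 in the other Con-TAC libraries. Of the Tg-TAC libraries 5 carried 7 to 14, and Tg-TAC 6 carried 29. The sham libraries carried 9 to 14 or 29 to 31. The library descriptions end in another number, after the letter S, whose meaning is also not given. It ran from 1 to 12 without repeats in the vehicle TAC libraries. With repeats, it ran from 6 to 13 in the sham libraries and from 6 to 14 in the MitoQ libraries.

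Sirt4, the gene the label names, was not detectably higher in the libraries labelled cSirt4-Tg in any of the 3 treatments. Sirt4 (ENSMUSG00000029524, mm39 chromosome 5, 115616069 to 115622784) averaged 411.7 ± 96.6 normalized counts in Con-Sham and 377.2 ± 48.0 in Tg-Sham (SD, n = 6 each; log2 Tg minus Con -0.11, exact permutation test, two-sided, p = 0.539, adjusted p = 0.742). After TAC it averaged 341.0 ± 49.6 in Con and 361.8 ± 57.8 in Tg (log2 0.09, exact p = 0.528, adjusted p = 0.742). With MitoQ it averaged 353.2 ± 18.6 in Con and 349.2 ± 22.5 in Tg (log2 -0.02, exact p = 0.742, adjusted p = 0.742). Each difference was smaller than the spread between the libraries. The smallest p that 6 against 6 libraries allow is 0.00216. The genotype names in all comparisons are therefore those of the labels.

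**Figure D1:**
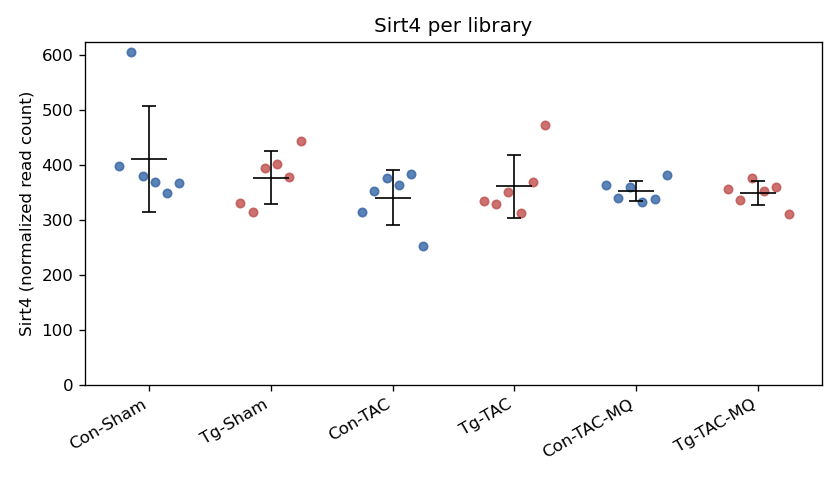
Sirt4 in normalized read counts (vertical axis) for each library of the 6 groups (horizontal axis); blue points are Con libraries, red points are Tg libraries, and bars give the mean ± SD of 6 libraries. The groups overlap in each treatment, with 349 to 606 in Con-Sham beside 314 to 444 in Tg-Sham.

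To establish which genes changed with TAC in control hearts, Con-TAC was compared with Con-Sham. Acta1 (ENSMUSG00000031972, mm39 chromosome 8, 124618508 to 124621490), the skeletal muscle actin that the stressed heart re-expresses, rose from 6622 ± 2807 to 78870 ± 32970 normalized counts (log2 3.54, SE 0.57, limma adjusted p = 0.000824, higher in 6 of 6 libraries). Ankrd1, a stress-responsive cardiac ankyrin repeat protein, rose by log2 1.60 (SE 0.33, adjusted p = 0.00774, 6 of 6). Among the 20 fetal and hypertrophy genes, 8 rose and none fell, and 14 were higher adjusted over the list alone. Camera gave that list an adjusted p = 4.36e-08, and adjusted p = 0.312 with an estimated correlation. Of 43 matrix genes 11 rose and none fell, with 26 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.43e-14, adjusted p = 0.439 with an estimated correlation). Cilp, a matrix protein, rose from 185.9 ± 51.7 to 2437 ± 2675 (log2 3.09, SE 0.62, adjusted p = 0.00618, 6 of 6). Edn3, which encodes endothelin 3, was 405.2 ± 314.5 against 60.9 ± 19.8 (log2 2.50, SE 0.50, adjusted p = 0.00603, 6 of 6). The TGF-beta and myofibroblast list that holds Edn3 had 5 of 33 members higher and 1 lower, 14 and 1 adjusted over the list alone (camera adjusted p = 8.66e-06, adjusted p = 0.457 with an estimated correlation). The matrix metalloproteinase Mmp23 rose by log2 1.07 (SE 0.24, adjusted p = 0.0114, 6 of 6). The mean log2 value of the fibroblast markers, which share members with the matrix list, was 10.72 to 11.31 in Con-TAC and 10.52 to 10.69 in Con-Sham.

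In the same comparison 5 of 6 erythroid markers rose, 6 adjusted over the list alone (camera adjusted p = 5.85e-06, adjusted p = 0.312 with an estimated correlation). They included Alas2, an enzyme of haem synthesis (log2 1.16, SE 0.26, adjusted p = 0.0129, higher in 6 of 6 libraries). Bdh1, which oxidises the ketone body beta-hydroxybutyrate, rose from 3206 ± 671.2 to 7012 ± 1526 (log2 1.12, SE 0.20, adjusted p = 0.00209, 6 of 6). Of 20 cardiomyocyte maturity and calcium handling genes limma called none over all genes, and 5 were lower adjusted over the list alone (camera, lower, adjusted p = 0.000678, adjusted p = 0.467 with an estimated correlation). Of 40 fatty acid genes 2 fell and 1 rose, 5 and 1 adjusted over the list alone (camera, lower, adjusted p = 0.000252, adjusted p = 0.530 with an estimated correlation), and of 26 TCA cycle genes 19 were negative with none called (adjusted p = 0.0122, adjusted p = 0.617 with an estimated correlation). Without Con-TAC 6 neither passed (adjusted p = 0.110 and 0.440), and the TCA cycle list turned direction with the name number class in the model (0.649). The same library carried the calls of the interferon-stimulated genes (camera, higher, adjusted p = 0.00433, and 0.642 without it), cytokines (0.0103 and 0.263), macrophage markers (0.00773 and 0.0575) and, lower, Schwann markers (0.0113 and 0.0528), of which limma called 1 Schwann marker and no other member. With an estimated correlation these 4 lists had adjusted p = 0.457 or 0.530. The small nuclear RNA Rn7sk (ENSMUSG00002076161, mm39 chromosome 9, 78082585 to 78082915), which restrains transcription elongation, fell from 4568 ± 2479 to 66.9 ± 38.7 (log2 -6.03, SE 0.41, adjusted p = 7.91e-12, lower in 6 of 6 libraries). Another small RNA, Scarna2, was at least 45.9 in Con-Sham and lower in every Con-TAC library. Within the sham groups Rn7sk rose with Rn18s-rs5 (r = 0.983). A difference in library preparation cannot be told apart from the surgery here, so the fall of Rn7sk may not be a response to TAC. Over all 16275 genes limma called 863, of which 431 were higher and 432 lower, with at least 2-fold change in 178 and 80. The count was 134 without Con-TAC 4, 370 without Con-Sham 4, 387 without Con-Sham 6, 404 without Con-Sham 5, 420 without Con-Sham 3, 449 without Con-TAC 3, 574 without Con-Sham 1 and 1543 without Con-TAC 1. It was 166 with the name number class in the model and 24 in the 8 libraries named 7 to 14, and scaling to the same total outside the mitochondrial genome moved the median of all genes by log2 0.10 and put 83.6% of the calls higher instead of 49.9%.

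**Figure D2:**
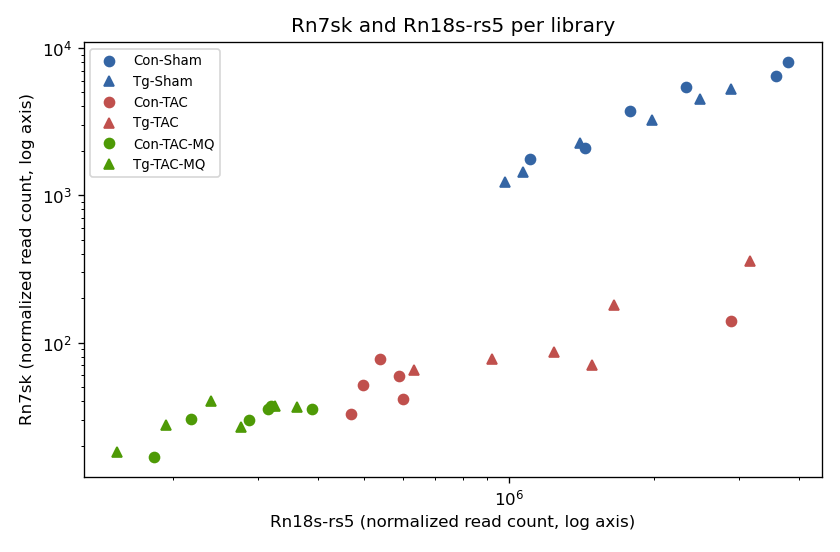
Rn7sk (vertical axis) against Rn18s-rs5 (horizontal axis), both in normalized read counts on log axes, with 1 point per library; blue is sham, red vehicle TAC and green MitoQ, circles are Con and triangles are Tg. Rn7sk was at least 1228 in the sham libraries and at most 359.3 in the TAC libraries.

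In hearts labelled cSirt4-Tg, TAC went with higher matrix genes and lower genes of fatty acid use, although none of the 20 lists that camera called passed an exact permutation of its means. Eln, which encodes elastin (ENSMUSG00000029675, mm39 chromosome 5, 134731447 to 134776177), rose from 1047 ± 294.3 in Tg-Sham to 2823 ± 1080 in Tg-TAC (log2 1.38, SE 0.24, limma adjusted p = 0.000712, higher in 6 of 6 libraries). Sparc, a collagen-binding matrix protein, rose by log2 1.15 (SE 0.22, adjusted p = 0.00114, 5 of 6). Of 43 matrix genes 31 rose and 2 fell, 38 and 2 adjusted over the list alone (camera adjusted p = 3.75e-17, adjusted p = 0.411 with an estimated correlation). Of 33 TGF-beta and myofibroblast genes 17 rose and 1 fell, 20 and 1 adjusted over the list alone (camera adjusted p = 1.08e-09, adjusted p = 0.411 with an estimated correlation). They included the transcription factor Meox1 (log2 2.12, SE 0.38, adjusted p = 0.000956, 6 of 6) and the TGF-beta inhibitor Smad7 (log2 0.88, SE 0.18, adjusted p = 0.00205, 6 of 6). Among 40 genes of fatty acid uptake and oxidation 19 fell and 1, Bdh1, rose, with 26 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.69e-09, adjusted p = 0.411 with an estimated correlation). Acacb, whose product makes malonyl-CoA at the mitochondria, fell from 10000 ± 1554 to 6243 ± 2594 (log2 -0.74, SE 0.16, adjusted p = 0.00354, lower in 5 of 6 libraries). Ppargc1a, a coactivator of mitochondrial genes, fell by 0.81 on the log2 scale (SE 0.19, adjusted p = 0.00494, 5 of 6).

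Other groups moved in the same hearts. Of 26 genes of the TCA cycle and pyruvate oxidation 8 fell and none rose, 16 lower adjusted over the list alone (camera adjusted p = 3.72e-06, adjusted p = 0.411 with an estimated correlation). Of 20 cardiomyocyte maturity and calcium handling genes 11 fell, 13 adjusted over the list alone (camera adjusted p = 2.62e-05, adjusted p = 0.411 with an estimated correlation). Pln, which encodes the calcium pump inhibitor phospholamban, fell by 0.76 on the log2 scale (SE 0.18, adjusted p = 0.00556, lower in 5 of 6 libraries). Abcc9, a subunit of the ATP-sensitive potassium channel, fell from 12020 ± 979.0 to 5497 ± 2754 (log2 -1.26, SE 0.20, adjusted p = 0.000346, 6 of 6). Of 27 genes of the integrated and mitochondrial stress response 7 rose and 1 fell, 10 and 1 adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.411 with an estimated correlation). Atf4, its transcription factor, rose by log2 0.58 (SE 0.13, adjusted p = 0.00387, 6 of 6). Of 35 antioxidant genes 8 rose and none fell, 10 and 1 adjusted over the list alone (camera adjusted p = 0.00476, adjusted p = 0.411 with an estimated correlation). Txn1, which encodes thioredoxin, rose by log2 0.39 (SE 0.10, adjusted p = 0.00861, 6 of 6). The cell type markers moved as well: of 12 cardiomyocyte markers 4 fell, 5 adjusted over the list alone (median log2 -0.39, camera adjusted p = 0.000968, adjusted p = 0.411 with an estimated correlation). Of 16 fibroblast markers 7 rose and 2 fell, 8 and 2 adjusted over the list alone (camera adjusted p = 0.0358, adjusted p = 0.428 with an estimated correlation), and that list did not pass without Tg-TAC 1 (adjusted p = 0.127), Tg-Sham 3 (0.0730) or Tg-TAC 5 (0.0694). Adipocyte markers were also higher (median log2 1.49, camera adjusted p = 0.0368, adjusted p = 0.411 with an estimated correlation), and the adipocyte hormone Adipoq was 2678 in Tg-TAC 4 and at most 29.7 in the other Tg-TAC libraries. The adipocyte list did not pass without Tg-TAC 4 (adjusted p = 0.317), Tg-Sham 3 (0.0730) or Tg-TAC 6 (0.0637). Limma called 2716 genes, 1288 higher and 1428 lower. The count was 1693 without Tg-TAC 4, 1718 without Tg-TAC 5 and 4606 without Tg-TAC 6, and 712 with only the 12 libraries compared.

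The TAC effect was then compared between the genotypes. Of the 863 and 2716 genes called in Con and Tg, 500 were called in both and in the same direction, none in opposite directions, where independent calls would share 72.0. For single genes the difference between the effects was not detectable in limma or edgeR. Limma called 0 genes in the interaction (949 at an unadjusted p under 0.05, smallest adjusted p = 0.178), edgeR called 0 and DESeq2 called 2, Abat (adjusted p = 0.00975) and Eps8l1 (0.0455), the latter chosen after its values were seen. Limma with array weights called 3. Abat, an enzyme that breaks down GABA, had the smallest p in limma (log2 difference -1.51, SE 0.29, adjusted p = 0.178). The 12 mitochondrially encoded genes had a lower median in the interaction (log2 -0.50, none positive, 4 lower adjusted over the list alone, camera adjusted p = 8.50e-07, adjusted p = 0.814 with an estimated correlation). The 22 cell cycle genes had a higher median (log2 0.57, 20 positive, camera adjusted p = 0.000108, adjusted p = 0.846 with an estimated correlation).

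**Figure D3:**
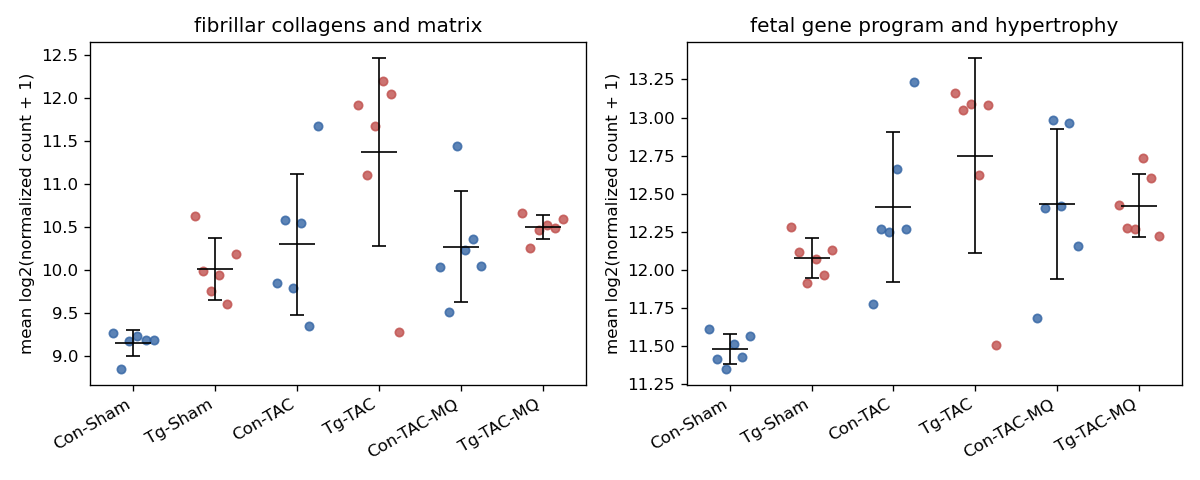
Mean log2(normalized count + 1) over the 43 matrix genes (left) and the 20 fetal and hypertrophy genes (right) for each library of the 6 groups; blue points are Con, red points are Tg, and bars give the mean ± SD of 6 libraries. Tg-TAC 6 lies at 9.28 and 11.50, below the other Tg-TAC libraries at 11.11 to 12.20 and 12.62 to 13.16.

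To see what accompanied the cSirt4-Tg label without TAC, Tg-Sham was compared with Con-Sham. Macrophage genes were higher in the hearts labelled cSirt4-Tg. Ccr2, the chemokine receptor of recruited monocytes, was 307.3 ± 90.8 normalized counts in Tg-Sham and 50.4 ± 22.6 in Con-Sham (log2 2.65, SE 0.49, limma adjusted p = 0.00516, higher in 6 of 6 libraries). Csf1r, the receptor for macrophage colony-stimulating factor, was 1977 ± 182.1 and 1167 ± 173.3 (log2 0.77, SE 0.14, adjusted p = 0.00437, 6 of 6). Mmp12, a macrophage elastase, was 91.6 ± 35.4 and 8.21 ± 6.69 (log2 3.55, SE 0.53, adjusted p = 0.000316, 6 of 6). Of 20 macrophage markers 9 were higher and none lower, 16 adjusted over the list alone (camera adjusted p = 1.45e-16, adjusted p = 0.102 with an estimated correlation). Of 27 cytokines and chemokines 2 were higher, 9 adjusted over the list alone (camera adjusted p = 7.34e-08, adjusted p = 0.414 with an estimated correlation). Of 11 NADPH oxidase and other reactive oxygen genes 1, Cybb, was higher, 3 and 1 lower adjusted over the list alone (camera adjusted p = 0.00171, adjusted p = 0.311 with an estimated correlation). Cybb, the phagocyte oxidase subunit, was 677.9 ± 96.5 and 322.4 ± 101.9 (log2 1.12, SE 0.26, adjusted p = 0.0277, 6 of 6), and lost the call without Tg-Sham 1, 2, 4 or 6 or Con-Sham 2, 3 or 5 (adjusted p 0.0549 to 0.0971).

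As lists, matrix genes stood higher and genes of the TCA cycle and of fatty acid use lower in Tg-Sham, while limma called 1 of these matrix genes and none of the others. Of 43 matrix genes 42 had a positive difference and 1 was called, 12 adjusted over the list alone (camera adjusted p = 1.69e-13, adjusted p = 0.414 with an estimated correlation). Of 16 fibroblast markers all were positive and 1 was called, 12 adjusted over the list alone (camera adjusted p = 2.25e-09, adjusted p = 0.102 with an estimated correlation). The 26 TCA cycle genes were all negative, with no call for a single gene (median log2 -0.18, camera adjusted p = 2.36e-05, adjusted p = 0.605 with an estimated correlation). The 12 cardiomyocyte markers were also all negative with no call (median log2 -0.18, camera adjusted p = 0.00847, adjusted p = 0.632 with an estimated correlation). The 40 fatty acid genes had a median of log2 -0.23 and no call (camera adjusted p = 3.37e-06, adjusted p = 0.605 with an estimated correlation). Dmd, which encodes dystrophin (ENSMUSG00000045103, mm39 chromosome X, 81992476 to 84249747), was 1374 ± 215.8 against 3015 ± 195.0 (log2 -1.15, SE 0.16, limma adjusted p = 0.000119, lower in 6 of 6 libraries). Exoc2, a subunit of the exocyst (ENSMUSG00000021357, mm39 chromosome 13, 30997902 to 31158076), was 338.9 ± 36.3 against 634.8 ± 61.0 (log2 -0.90, SE 0.09, adjusted p = 4.18e-07, 6 of 6). Limma called 142 genes, 128 higher and 14 lower. The count was 29 without Tg-Sham 6, 49 without Con-Sham 2, 53 without Con-Sham 3, 58 without Tg-Sham 1, 59 without Tg-Sham 4, 62 without Tg-Sham 2, 78 without Con-Sham 5, 84 without Con-Sham 4 or Tg-Sham 5 and 86 without Con-Sham 1. The 6 libraries named 7 to 14 gave 24 genes, and the replicate number as a block gave 92. Other alternatives gave more: 241 with the name number class in the model, 321 with DESeq2, 879 with only the libraries compared and 1069 with array weights.

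To see what accompanied the label after TAC, Tg-TAC was compared with Con-TAC. Matrix genes were higher in Tg-TAC, in a comparison where 7 of 100 splits of the libraries called as many genes and no list passed an exact permutation of its means. Col6a1, a chain of collagen VI (ENSMUSG00000001119, mm39 chromosome 10, 76544626 to 76562002), was 5192 ± 1814 normalized counts against 2905 ± 472.0 (log2 0.77, SE 0.17, limma adjusted p = 0.0127, higher in 5 of 6 libraries). Acta2, the smooth muscle actin of myofibroblasts, was 6053 ± 1483 against 2347 ± 1122 (log2 1.46, SE 0.30, adjusted p = 0.00839, 6 of 6). All 43 matrix genes had a positive difference, 11 were called higher and 31 adjusted over the list alone (camera adjusted p = 4.62e-16, adjusted p = 0.361 with an estimated correlation). Of 28 cross-linking and remodelling enzymes 11 were higher, 16 and 1 lower adjusted over the list alone (camera adjusted p = 5.16e-07, adjusted p = 0.361 with an estimated correlation). Pcolce, which enhances procollagen processing, differed by log2 0.95 (SE 0.21, adjusted p = 0.0130, 5 of 6). Of 20 macrophage markers 8 were higher, 15 adjusted over the list alone (camera adjusted p = 1.48e-09, adjusted p = 0.361 with an estimated correlation). The 22 cell cycle genes had no single call over all genes and 10 adjusted over the list alone (camera, higher, adjusted p = 3.02e-06, adjusted p = 0.361 with an estimated correlation).

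Genes of fatty acid use, of the TCA cycle and of the mitochondrial genome were lower in Tg-TAC than in Con-TAC. The same limit holds from the splits of the libraries and the permutation of list means. Of 40 fatty acid genes 12 were lower and none higher, 26 adjusted over the list alone (camera adjusted p = 5.32e-12, adjusted p = 0.361 with an estimated correlation). Esrrg, a nuclear receptor that drives mitochondrial genes, was 1054 ± 224.1 against 1523 ± 149.3 (log2 -0.55, SE 0.11, limma adjusted p = 0.00980, lower in 6 of 6 libraries). Of 26 TCA cycle genes 6 were lower, 19 adjusted over the list alone (camera adjusted p = 4.27e-10, adjusted p = 0.361 with an estimated correlation). Of 12 mitochondrially encoded genes 8 were lower, 11 adjusted over the list alone (camera adjusted p = 6.95e-09, adjusted p = 0.361 with an estimated correlation). Among them mt-Co3, a subunit of cytochrome oxidase (ENSMUSG00000064358, mm39 MT, 8607 to 9390), was 118.8 ± 56.3 against 318.1 ± 68.2 (log2 -1.48, SE 0.22, adjusted p = 0.000348, 6 of 6). Another subunit, mt-Co1, took 4.28% to 8.64% of the reads in these 12 libraries, so the counts at mt-Co3 are very small beside it. They may not measure the expression of the gene, and the cause was not tested. The 12 cardiomyocyte markers were all negative with 2 called, 8 adjusted over the list alone (camera adjusted p = 3.43e-05, adjusted p = 0.361 with an estimated correlation). Limma called 1054 genes, 519 higher and 535 lower. With only these 12 libraries in the fit 1 gene was called, Maged2 (log2 0.82, adjusted p = 0.00684, chosen after its values were seen), so the count rests on the spread pooled over all 6 groups. The count was 134 without Tg-TAC 4, 176 without Con-TAC 3, 260 without Con-TAC 5, 299 without Con-TAC 1, 300 without Tg-TAC 1, 320 without Tg-TAC 5, 648 without Tg-TAC 3, 652 without Con-TAC 2, 2812 without Con-TAC 6 and 3642 without Tg-TAC 6. It was 4103 in the 10 libraries named 7 to 14, and median-centred values put 37.3% of the calls higher where 49.2% were higher without centring.

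In MitoQ-treated hearts the label went with 12 genes in limma, 8 higher and 4 lower in Tg-TAC-MQ than in Con-TAC-MQ. Ndnf, a secreted neurotrophic factor (ENSMUSG00000049001, mm39 chromosome 6, 65648574 to 65689310), was 641.0 ± 117.8 normalized counts against 196.7 ± 58.9 (log2 1.72, SE 0.20, limma adjusted p = 6.64e-06, higher in 6 of 6 libraries). Klhdc7a was 502.0 ± 107.6 against 191.3 ± 32.0 (log2 1.38, SE 0.20, adjusted p = 0.000176, 6 of 6). Lyz1, a lysozyme gene, was 147.7 ± 46.9 against 18.0 ± 14.4 (log2 3.34, SE 0.57, adjusted p = 0.00263, 6 of 6). Dmd (log2 -1.28, SE 0.16), Exoc2 (log2 -0.78, SE 0.09), Polr3g (log2 -0.82, SE 0.14) and Ssbp2 (log2 -0.67, SE 0.10) were the 4 lower genes, each lower in 6 of 6 libraries, with adjusted p from 7.13e-06 to 0.00246. Mgl2, Mmp12, Sema4a, Ndrg4 and Atp6v0e2 completed the 12, each higher in 6 of 6 libraries. Their calls depended on single libraries. Mgl2 lost it without Con-TAC-MQ 2 or Tg-TAC-MQ 2 or 3 (adjusted p 0.0762 to 0.0957) and Mmp12 without Con-TAC-MQ 1, 2 or 6 or Tg-TAC-MQ 1, 2 or 3 (0.0548 to 0.0963). Sema4a (0.0509 to 0.164) and Ndrg4 (0.0542 to 0.114) lost it without Con-TAC-MQ 1 or 2 or any Tg-TAC-MQ library, and Atp6v0e2 (0.0753 to 0.164) also without Con-TAC-MQ 4 or 6. Of 20 macrophage markers 19 were positive, none was called and 2 were called adjusted over the list alone (camera adjusted p = 6.40e-12, adjusted p = 0.202 with an estimated correlation). The 16 fibroblast markers were all positive, none was called and 2 were called adjusted over the list alone (camera adjusted p = 4.10e-10, adjusted p = 0.103 with an estimated correlation). None of the 11 lists that camera called in this comparison passed an exact permutation of its means. Of the 12 genes 11 were also called in the same direction in sham hearts, where independent calls would share 0.0664, and the 2 comparisons have no library in common. Likewise 46 of the 142 genes called in sham hearts were called in the same direction after TAC, against 4.54 for independent calls. The count was 64 without Con-TAC-MQ 3, 7 without Con-TAC-MQ 2, Tg-TAC-MQ 2 or Tg-TAC-MQ 3, and 27 with only the libraries compared.

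To see which genes differed with MitoQ after TAC in control hearts, Con-TAC-MQ was compared with Con-TAC. Atm, a DNA damage kinase (ENSMUSG00000034218, mm39 chromosome 9, 53350449 to 53448040), was 423.0 ± 46.8 normalized counts with MitoQ and 211.4 ± 128.5 with vehicle (log2 1.20, SE 0.24, limma adjusted p = 0.00762, higher in 6 of 6 libraries). mt-Co3 was 139.1 ± 28.4 and 318.1 ± 68.2 (log2 -1.18, SE 0.22, adjusted p = 0.00391, lower in 6 of 6). mt-Co2, another cytochrome oxidase subunit, was 205.8 ± 34.8 and 525.4 ± 106.3 (log2 -1.34, SE 0.24, adjusted p = 0.00391, 6 of 6), and Cox5b-ps, a pseudogene, differed by log2 -1.34 (SE 0.22, adjusted p = 0.00133, 6 of 6). The subunit mt-Co1 took 5.90% to 8.64% of the reads in these libraries, so the counts at mt-Co3 and mt-Co2 are very small beside it. Whether they measure the expression of these genes was not tested. Of 12 mitochondrially encoded genes 3 were lower, also 3 adjusted over the list alone (camera adjusted p = 0.000138, adjusted p = 0.971 with an estimated correlation). That list holds mt-Co2 and mt-Co3 and carries the same limit. Genes of the mitochondrial genome together took 17.3% to 24.9% of the reads in Con-TAC and 16.6% to 23.2% in Con-TAC-MQ. These ranges overlap, so the list call does not show a lower mitochondrial share of the reads. Of 69 nuclear respiratory chain genes none was called, and 66 were negative (median log2 -0.23, camera adjusted p = 2.82e-09, adjusted p = 0.971 with an estimated correlation). Of 35 antioxidant genes 1, Gpx4, was lower, also 1 adjusted over the list alone (camera adjusted p = 0.000282, adjusted p = 0.310 with an estimated correlation), and Gpx4 lost its call without Con-TAC 2, 3, 4 or 5 or Con-TAC-MQ 1, 2, 3, 5 or 6 (adjusted p 0.0584 to 0.141). The 43 matrix genes held no call and had a median of log2 0.07 (camera adjusted p = 0.900). None of the 3 lists that camera called in this comparison passed an exact permutation of its means. Limma called 526 genes, 313 higher and 213 lower. The count was 48 without Con-TAC 4, 113 without Con-TAC 5, 134 without Con-TAC 3, 137 without Con-TAC 2, 175 without Con-TAC-MQ 6, 194 without Con-TAC-MQ 2, 197 without Con-TAC-MQ 5, 308 without Con-TAC-MQ 1, 980 without Con-TAC 1 and 1756 without Con-TAC 6. It was 26 with only the 12 libraries compared. With the name number class in the model it was 225, of which 4 were among the 526, and 7 lists turned direction, among them the respiratory chain (adjusted p = 3.55e-16), matrix (3.13e-09) and mitochondrially encoded lists (0.589). MitoQ cannot be told apart from that class here, since Con-TAC 6 alone of the vehicle TAC libraries shares it, and Rn18s-rs5 also differed between the groups (log2 -1.36, SE 0.38, adjusted p = 0.0429, lower in 6 of 6). Rn18s-rs5 lost that call without Con-TAC 2 (log2 -0.95, adjusted p = 0.129), and without Con-TAC 3, 4 or 5 or Con-TAC-MQ 1, 2, 3, 5 or 6 (adjusted p 0.0568 to 0.101). Scaling to the same total outside the mitochondrial genome put 84.4% of the calls higher instead of 59.5%.

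In hearts labelled cSirt4-Tg, MitoQ went with lower matrix genes and higher genes of fatty acid use, although none of the 15 lists that camera called passed an exact permutation of its means. Ppara, the nuclear receptor for fatty acids (ENSMUSG00000022383, mm39 chromosome 15, 85619184 to 85687020), was 1054 ± 132.5 normalized counts in Tg-TAC-MQ and 380.3 ± 109.9 in Tg-TAC (log2 1.51, SE 0.28, limma adjusted p = 0.000655, higher in 6 of 6 libraries). Of 40 fatty acid genes 10 rose and none fell, 14 and 1 adjusted over the list alone (camera adjusted p = 1.64e-06, adjusted p = 0.699 with an estimated correlation). Of 43 matrix genes 11 fell and none rose, 12 adjusted over the list alone (camera adjusted p = 1.64e-06, adjusted p = 0.699 with an estimated correlation). Sparc fell from 23730 ± 7576 to 12040 ± 1576 (log2 -0.90, SE 0.22, adjusted p = 0.00515, 6 of 6), and Comp, a cartilage matrix protein, fell from 4098 ± 4453 to 132.1 ± 70.6 (log2 -3.92, SE 1.00, adjusted p = 0.00753, 6 of 6). Of 33 TGF-beta and myofibroblast genes 15 fell and 1 rose, 18 and 1 adjusted over the list alone (camera adjusted p = 5.14e-06, adjusted p = 0.576 with an estimated correlation). Meox1 fell by 1.42 on the log2 scale (SE 0.38, adjusted p = 0.0106, 6 of 6). Of 35 antioxidant genes 9 fell and none rose, 11 adjusted over the list alone (camera adjusted p = 8.78e-05, adjusted p = 0.244 with an estimated correlation). Txn1 fell from 1554 ± 72.2 to 1097 ± 70.3 (log2 -0.50, SE 0.10, adjusted p = 0.00102, 6 of 6).

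Calcium handling and stress genes also differed between Tg-TAC-MQ and Tg-TAC. Of 20 cardiomyocyte maturity and calcium handling genes 10 rose, 13 and 1 lower adjusted over the list alone (camera adjusted p = 6.77e-05, adjusted p = 0.576 with an estimated correlation). Cacna1c, the L-type calcium channel, rose by log2 0.59 (SE 0.14, limma adjusted p = 0.00504, higher in 6 of 6 libraries). Of 27 integrated and mitochondrial stress genes 7 fell and 1 rose, 8 and 1 adjusted over the list alone (camera adjusted p = 0.000941, adjusted p = 0.576 with an estimated correlation), among them Atf4 (log2 -0.56, SE 0.13, adjusted p = 0.00368, 6 of 6). Of 19 interferon-stimulated genes 18 were negative and 2 were called, 1 adjusted over the list alone (camera adjusted p = 0.00176, adjusted p = 0.699 with an estimated correlation). Of 7 Schwann and neuronal markers 4 rose, 5 adjusted over the list alone (camera adjusted p = 0.000941, adjusted p = 0.576 with an estimated correlation). Of 8 adipocyte markers 1 fell and all were negative, 2 adjusted over the list alone (median log2 -1.13, camera adjusted p = 0.0411, adjusted p = 0.662 with an estimated correlation). That list did not pass without Tg-TAC 4 (adjusted p = 0.432), where Adipoq was 2678, Tg-TAC 6 (0.0608) or Tg-TAC-MQ 1 (0.0589), 2 (0.0642) or 3 (0.0823). Of 12 cardiomyocyte markers 2 rose, also 2 adjusted over the list alone, and 10 were positive (median log2 0.20, camera adjusted p = 0.145, and 0.0118 without Tg-TAC 6). Limma called 2821 genes, 1610 higher and 1211 lower, and 4444 without Tg-TAC 6. With the name number class in the model it called 2551, of which 728 were among the 2821, and the same non-mitochondrial total put 85.2% of the calls higher instead of 57.1%. In the fit with the class, the shift for the names 20 and 21 rests on Con-TAC 6, a control heart. Rn18s-rs5 was lower by log2 -2.42 (SE 0.38, adjusted p = 0.000179, 6 of 6), and 5 of the 6 Tg-TAC libraries were named 7 to 14 where all Tg-TAC-MQ libraries were named 20 or 21.

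MitoQ was finally set against TAC within each genotype. In Tg hearts 1614 of the 2716 genes called with TAC (59.4%) were called in the opposite direction with MitoQ and 3 in the same direction. They comprised 671 of the 1288 genes higher with TAC and 943 of the 1428 lower ones. In control hearts 131 of 863 (15.2%) were called in the opposite direction and 3 in the same direction. Independent calls would give 237 opposite calls in Tg and 13.9 in control hearts. MitoQ called 2821 genes in Tg and 526 in control hearts, so the percentages do not compare the size of a reversal. Whatever the MitoQ call, the sign was opposite for 395 of 431 higher and 408 of 432 lower genes in control hearts. In Tg hearts it was opposite for 1282 of 1288 and 1414 of 1428. Both contrasts use the same TAC libraries, which alone gives a negative covariance. In Tg hearts the covariance of the log2 differences across genes was -0.233, below the range of 100 simulated draws without effects (mean -0.0866, -0.142 to 0.000163), and it was -0.142 on average (-0.173 to -0.0857) when 20 splits gave each contrast its own 3 TAC libraries. In control hearts it was -0.100, inside the simulated range (mean -0.0618, -0.126 to 0.00618), and -0.0367 (-0.0792 to 0.0310) with the split libraries. Genes are not independent replicates. Anything common to the vehicle TAC libraries, such as their name numbers or preparation, enters both contrasts even with split libraries. The simulated draws without effects do not hold it either. Neither reference can therefore separate a reversal of TAC by MitoQ from such a difference of the vehicle TAC libraries. With the name number class in the model 900 genes in Tg and 0 in control hearts were called in opposite directions.

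Whether the MitoQ difference itself differed between genotypes was tested by the interaction. For single genes limma and edgeR detected no difference. Limma called 0 genes (1377 at an unadjusted p under 0.05), edgeR 0, DESeq2 16, limma with array weights 159 and limma with the name number class 17, and mt-Co3 had the smallest p (log2 1.56, SE 0.30, limma adjusted p = 0.0612). Its counts carry the limit given above. The count was 7 without Con-TAC 6, 10 without Tg-TAC 2 and 23 without Tg-TAC 6. Of 43 matrix genes 42 were negative (median log2 -0.83, camera adjusted p = 1.89e-09, adjusted p = 0.562 with an estimated correlation). Of 69 nuclear respiratory chain genes 68 were positive (median log2 0.22, camera adjusted p = 4.20e-07, adjusted p = 0.594 with an estimated correlation). The 20 cardiomyocyte maturity and calcium handling genes were all positive (median log2 0.35, camera adjusted p = 3.21e-05, adjusted p = 0.562 with an estimated correlation). Apart from Tg-TAC 6 and Con-TAC 6, the vehicle TAC libraries of both genotypes shared a name number class, as did all MitoQ libraries. A class shift that is the same in both genotypes therefore largely cancels in this test. What is left of it rests on Tg-TAC 6 and Con-TAC 6. A shift that differs between the genotypes would stay in the test.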

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

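The groups of 6 libraries and the interactions were examined by rules fixed before the values were seen, while the tests of explanations for Rn7sk, Tg-TAC 6 and Sirt4 were chosen after these patterns were seen. A library stood apart when its distance to the nearest other library, divided by the range of its 6 libraries, passed Dixon's 95% critical value for 6 samples. Chance passes that value in about 5% of the groups. It was passed in 75 of 477 groups where chance gives 23.8, which were 30 of 243 for named genes (12.2 by chance), 41 of 210 for list means (10.5) and 4 of 24 for library measures (1.20). Every number in the next 5 paragraphs that follows a gene or list without a unit is this ratio. Libraries share a heart across genes, so the counts are not independent.

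Con-TAC 6 stood apart 15 times and was kept in all fits unless stated. The interferon-induced chemokine Cxcl9 was higher than in the other Con-TAC libraries (log2 value 9.69 against at most 7.20, ratio 0.811), as were the means of the interferon-stimulated genes (0.900), the mesothelial markers (0.772) and the atrial markers (0.677), Pak3 (0.660) and Atp8a2 (0.631). The mitochondrially encoded genes were lower in it as a list (0.804) and for mt-Co3 (0.750), mt-Co2 (0.721) and mt-Atp6 (0.689), with the pseudogene Cox5b-ps (0.684), the nuclear respiratory chain list (0.633), the cardiomyocyte markers (0.653), Plekhh1 (0.696) and Lvrn (0.629). It is the vehicle TAC library whose name carries the number 20.

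Tg-TAC 6 stood apart 10 times. The keratin Krt18 was lower than in the other Tg-TAC libraries (log2 value 2.76 against at least 8.54, ratio 0.897), with the transcription factor Meox1 (0.628) and the means of the fetal and hypertrophy list (0.675), the atrial markers (0.656), the integrated and mitochondrial stress list (0.645), the NADPH oxidase list (0.636), the TGF-beta list (0.633) and the matrix list (0.627). The mitotic gene Cenpf (0.698) and the mean of the sirtuins (0.672) were higher in it. Tg-TAC 4 stood apart 7 times, always higher: the means of the mesothelial (0.831), lymphocyte (0.735) and neutrophil markers (0.669), the chemokines Cxcl13 (0.658) and Ccl8 (0.635), Mir6236 (0.777) and the share of reads at Rn18s-rs5 (11.84% against at most 5.57%, ratio 0.663).

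Con-TAC-MQ 3 stood apart 9 times and was kept in all fits unless stated. In it mt-Co2 (0.839), the cardiomyocyte markers (0.802), the sarcomere (0.724), the TCA cycle (0.733), the respiratory chain (0.666) and the fatty acid genes (0.632) were lower, and the cross-linking enzymes (0.750), the endoplasmic reticulum chaperones (0.735) and the cytokines (0.628) were higher. Con-TAC 2 had a higher share at Rn18s-rs5 (9.22% against at most 2.27%, ratio 0.906) and higher Rn18s-rs5 (0.864), AY036118 (0.700) and Rps24-ps3 (0.645).

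Among the sham libraries, Con-Sham 2 was higher for Sirt4 (0.761) and the cardiomyocyte markers (0.631) and lower for the matrix list (0.794), Dkk3 (0.667) and the lung markers (0.626). The lung mean in Con-Sham 2 was a log2 value of 0, with no read counted, so that flag lies at the floor. Con-Sham 1 was higher for Nmrk2 (0.719), the neutrophil markers (0.647) and the number of reads (0.654). Con-Sham 6 was higher for the NADPH oxidase list (0.789) and the interferon-stimulated genes (0.734) and lower for Acap3 (0.659), and Con-Sham 4 was higher for Cnmd (0.777). Tg-Sham 3 was lower for the atrial markers (0.690) and Cpxm2 (0.627), Tg-Sham 4 for Ttc9 (0.721), Tg-Sham 5 for the list of Xist and Y-linked genes (0.726) and Tg-Sham 6 for Dpyd (0.739).

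Of the remaining TAC libraries, Con-TAC 3 was lower for Acap3 (0.731) and the lung markers (0.689), and Con-TAC 1 for the endothelial markers (0.666). The lung mean in Con-TAC 3 was also a log2 value of 0, at the floor. Tg-TAC 1 was higher for the erythroid markers (0.682), Tg-TAC 2 for the number of reads (0.658) and Tg-TAC 3 for the smooth muscle markers (0.638). Tg-TAC-MQ 6 was lower for the sarcomere (0.860) and higher for the smooth muscle markers (0.815). Atrial markers were higher in Con-TAC-MQ 5 (0.727) and Tg-TAC-MQ 4 (0.656), the cardiomyocyte maturity list in Tg-TAC-MQ 2 (0.652) and Rps24-ps3 in Con-TAC-MQ 4 (0.707).

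The camera test of the interactions passed for 28 lists at the preset correlation, and for none of them with an estimated correlation (lowest adjusted p = 0.562 for MitoQ and 0.814 for TAC). Each number here is the median log2 difference between the effects in Tg and in Con. For TAC it was higher in the Tg hearts for the adipocyte markers (2.31), the cell cycle (0.57), the matrix list (0.30), the smooth muscle markers (0.26) and the TGF-beta list (0.17). It was lower for the erythroid markers (-0.81), the mitochondrially encoded genes (-0.50), the cardiomyocyte markers (-0.28), the fatty acid genes (-0.25), the TCA cycle (-0.19) and the respiratory chain (-0.12). For MitoQ it was higher for the Schwann markers (0.60), the mitochondrially encoded genes (0.60), the maturity list (0.35), the fatty acid genes (0.34), the cardiomyocyte markers (0.33), the TCA cycle (0.26) and the respiratory chain (0.22). It was lower for the neutrophil markers (-1.21), the cell cycle (-1.21), the matrix list (-0.83), the TGF-beta list (-0.57), the cytokines (-0.55), the cross-linking enzymes (-0.45), the macrophage markers (-0.27), the endoplasmic reticulum chaperones (-0.22), the integrated stress list (-0.21) and the immediate early genes (-0.15). Leaving out 1 library ended the call for 8 of the 11 TAC lists and 8 of the 17 MitoQ lists. For TAC the highest adjusted p was reached without Tg-TAC 4 for the cardiomyocyte markers (0.433), adipocyte markers (0.333), TCA cycle (0.294), matrix list (0.260), TGF-beta list (0.241) and fatty acid genes (0.125), and for the respiratory chain, which turned (0.803). It was 0.0557 without Tg-TAC 3 for the smooth muscle markers. Calls of these lists also ended without Con-TAC 1 to 5, Con-Sham 1, 3, 4, 5 or 6, Tg-Sham 3, 4 or 5 or Tg-TAC 1, 3 or 5 (adjusted p 0.0501 to 0.640). For MitoQ it was reached without Tg-TAC 4 for the neutrophil (0.229), Schwann (0.103) and cardiomyocyte markers (0.0783), without Con-TAC-MQ 3 for the macrophage markers (0.581), cytokines (0.121) and chaperones (0.0672), and without Tg-TAC-MQ 2 for the immediate early genes (0.198) and the integrated stress list (0.195). Calls of some of these 8 lists also ended without Con-TAC 1, 2, 3, 5 or 6, Con-TAC-MQ 3 to 6, any Tg-TAC library or Tg-TAC-MQ 1 to 5 (adjusted p 0.0507 to 0.272).

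Tg-TAC 6 had fetal and matrix lists near those of control sham hearts, at 11.50 and 9.28, against 11.35 to 11.62 and 8.84 to 9.26 in Con-Sham, 11.91 to 12.28 and 9.60 to 10.62 in Tg-Sham and 11.78 to 13.24 and 9.35 to 11.67 in Con-TAC. That it was a sham heart labelled Tg-TAC stays open. Rn7sk was 180.4 in it, at least 1228 in the sham libraries and 16.8 to 359.3 in the other TAC libraries. That counts against a sham heart only if Rn7sk follows the surgery and not the preparation. The name number of Tg-TAC 6, 29, lies in the range of 29 to 31 that otherwise only 6 sham libraries carry. The number after the letter S in its description goes with its label instead. That number lies below those of all sham libraries and fills a place in the unrepeated run of the vehicle TAC libraries. The meaning of that number is not given. That Tg-TAC 6 was a control heart labelled cSirt4-Tg stays open: on 11 genes that follow the label its mean signed log2 value was 0.409, between the highest of 18 controls (0.345) and the lowest of 17 other Tg libraries (0.510), whereas its median position of 0.175 lay among the controls (-0.216 to 0.195) and below the other Tg libraries (0.405 to 1.30). No Con-TAC library lay in the range of the other Tg libraries on either score (at most 0.345 and 0.161, both in Con-TAC 6), so no partner for an exchange inside the vehicle TAC groups stood out. The 0.345 of Con-TAC 6 lies close to the 0.409 of Tg-TAC 6, however. Con-TAC 6 also had the highest fetal (13.24) and matrix (11.67) lists of its group. An exchange of these libraries is therefore not excluded. A heart that saw little pressure overload stays open as well, since the fetal list is the pattern itself and no pressure is given in the sources used here, but Tg-TAC 6 also lay below every Tg-Sham library for the macrophage (7.52 against 7.97 to 8.52) and NADPH oxidase lists (7.22 against 7.76 to 8.05), which little overload alone leaves unaccounted for.

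Rn7sk was lower in the 24 TAC libraries than in the 12 sham libraries, with 0 of the TAC libraries at or above the lowest sham library. Ribosomal RNA left in the libraries is argued against as the whole cause: the log2 difference was -5.98, and -4.22 (SE 0.22) at equal Rn18s-rs5, although within the sham libraries Rn7sk rose with Rn18s-rs5 (n = 12, r = 0.983, rho = 0.972, permutation p = 3.00e-05, adjusted p = 4.50e-05, r = 0.975 without the 2 farthest libraries) and within the TAC groups too (n = 24, r = 0.822, rho = 0.767, permutation p = 2.00e-05, r = 0.693 without 2). A library preparation that differed between sham and TAC hearts cannot be told apart from the surgery, since no label separates them. Scarna2, another small RNA, went the same way, with at least 37.4 in the sham libraries and at most 41.3 in the TAC libraries. A response of the heart that follows the size of remodelling was not shown: within the 4 TAC groups r with the fetal list was -0.233 (n = 24, rho = -0.0913, permutation p = 0.382, r = -0.243 without 2), and this leaves open a response that is the same in each TAC heart. These were 3 relations, adjusted by Benjamini-Hochberg.

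Sirt4 was not higher in the libraries labelled cSirt4-Tg. Labels assigned at random are argued against, since 11 genes were called in the same direction between the genotypes in sham and in MitoQ hearts, which share no library, where independent calls would share 0.0664. Transcripts of a transgene that were not counted at Sirt4, for example those of another sequence than the mouse gene, are a candidate explanation that stays open: the log2 difference in sham hearts was -0.108, and the gene values hold no sequence to search. No test here addresses the protein.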

How the results depend on the processing

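Leaving out 4 doubted libraries (Tg-TAC 6, Tg-TAC 4, Con-TAC-MQ 5 and Con-Sham 2) and the permutation test of list means were chosen only after the data were seen, and Con-TAC 6 and Con-TAC-MQ 3, which also stood apart often, were kept. Counts of genes below are in the order of TAC in Con (863) and in Tg (2716), the label in sham (142), TAC (1054) and MitoQ hearts (12), MitoQ in Con (526) and in Tg hearts (2821), and the interactions with TAC (0) and with MitoQ (0), and a comparison left out of a sentence stayed within 1.5 times its count. Where no cause is named, the cause was not tested. Over all alternatives, named genes kept their side of the threshold in 7408 cases, lost the call in 1157, gained it in 21 and turned in 5. Lists kept their side in 8752 cases, lost the call in 350, gained it in 312 and turned in 18. A turn was counted only where the main fit or the alternative made a call. The kept cases may therefore hold changes of direction without a call. Of the counts and summaries 268 stayed and 97 moved.

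Leaving out 1 library in turn gave 134 to 1543 genes for TAC in Con, 1693 to 4606 for TAC in Tg, 29 to 149 for the label in sham, 134 to 3642 in TAC and 7 to 64 in MitoQ hearts, 48 to 1756 for MitoQ in Con, 2055 to 4444 for MitoQ in Tg, 0 for the interaction with TAC and 0 to 23 for that with MitoQ. In these fits the respiratory chain list of the TAC interaction ranged from adjusted p = 1.35e-09 without Con-TAC 6 to 0.803, and turned without Tg-TAC 4 (0.803). The cell cycle list of the label in MitoQ hearts ranged from 0.00164 to 0.830, and turned without Con-TAC-MQ 3 (0.00164). Without the 4 doubted libraries the counts were 1595 for TAC in Con, and 234, 2287 and 24 for the label in sham, TAC and MitoQ hearts.

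The class of the name number as a covariate gave 166 genes for TAC in Con, 241 and 3316 for the label in sham and TAC hearts, 225 for MitoQ in Con and 17 for the MitoQ interaction. Opposite calls of MitoQ and TAC became 0 in Con and 900 in Tg, with covariances of -0.0618 and -0.364. With it 4 genes turned for MitoQ in Con, Atp7a (log2 -0.12), Hipk2 (-0.50), Uprt (-0.21) and Zbed6 (-0.13), and Fabp4 turned for MitoQ in Tg (0.28). Lists turned too, for MitoQ in Con the respiratory chain (adjusted p = 3.55e-16), matrix (3.13e-09), TCA cycle (1.55e-07), cytokines (0.000144), cardiomyocyte markers (0.000310), cross-linking enzymes (0.00743) and mitochondrially encoded genes (0.589), for MitoQ in Tg the respiratory chain (1.14e-21), and for TAC in Con the respiratory chain (0.000379) and TCA cycle (0.649). The shift that this covariate assigns to the MitoQ libraries rests on a single vehicle TAC library, so these fits cannot separate MitoQ from the class. With the covariate MitoQ in Tg still gave 2551 genes, of which 728 were among the 2821 called without it. Only the libraries named 7 to 14, which are fewer, gave 24 genes for TAC in Con, and 24 and 4103 for the label in sham and TAC hearts.

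Array weights gave 3157, 4926, 1069, 3707, 405, 2870, 5761, 3 and 159 genes in the order above. With them the cell cycle (adjusted p = 0.0182) and endoplasmic reticulum chaperone (0.998) lists turned for the label in MitoQ hearts, and the latter for the MitoQ interaction (0.961). The 3 interaction genes were Mllt3, Acap3 and Gm16793. DESeq2 gave 1438 for TAC in Con, 321, 1752 and 27 for the label in sham, TAC and MitoQ hearts, 826 for MitoQ in Con, 2 for the TAC interaction (Abat and Eps8l1) and 16 for that with MitoQ. The cytokine list of the label in MitoQ hearts turned with DESeq2 (0.793) and edgeR (0.760). Fits of only the libraries compared, where the spread comes from fewer libraries, gave 712 for TAC in Tg, 879, 1 (Maged2) and 27 for the label in sham, TAC and MitoQ hearts and 26 for MitoQ in Con.

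Testing all listed genes without a filter gave 524 for TAC in Con, 620 and 19 for the label in TAC and MitoQ hearts, 323 for MitoQ in Con and 49 opposite calls in Con. A minimum of 50 gave a covariance of -0.0581 in Con and turned the neutrophil list of the label in MitoQ hearts (0.933). A pseudocount of 10 gave covariances of -0.0496 in Con and -0.136 in Tg, since it shrinks differences at low values. The same total outside the mitochondrial genome gave 816 genes for MitoQ in Con and 4 for the MitoQ interaction (mt-Co3, Gm10925, Gm28437 and Gm28661). The replicate number as a block, a pairing that the libraries did not show, gave 92 genes for the label in sham hearts.

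At the preset correlation 18 and 20 of 35 lists passed for TAC in Con and Tg, 14, 16 and 11 for the label in sham, TAC and MitoQ hearts, 3 and 15 for MitoQ in Con and Tg, and 11 and 17 for the interactions. With an estimated correlation 0 passed in camera for each of the 9, with lowest adjusted p from 0.102 to 0.814. An exact permutation of list means passed 14 lists for TAC in Con, 15 for the label in sham hearts and 0 for the other 5 comparisons. Sirt4 stayed undetected as higher in Tg in each alternative in which it was tested. Opposite calls in Tg hearts numbered at least 900 in the 8 alternatives run for them.

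Class covariate fits were run for all 9 contrasts, and fits of the libraries named 7 to 14 could not be run for the MitoQ contrasts, since no MitoQ library carries such a name. Depth sets a floor for rare genes: 16275 of 25626 listed genes reached a value of 10 in 6 libraries and the others were not tested, and the fewest reads, 14.8 M, were in Tg-TAC 4.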

Other observations

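Of the tests in this part, the search for genes that follow the label and the tests of chromosomes were chosen only after values had been seen, and what the splits of the libraries would show was written down after the real counts were seen. In all 3 treatments 62 genes differed between Tg and Con in the same direction at an unadjusted p under 0.01 in limma, 52 higher and 10 lower, where chance gives 0.00407. The genes named from them here were chosen after their values were seen, and each set of 3 values is the log2 difference in sham, TAC and MitoQ hearts. Fcgr2b, the inhibitory Fc receptor, was 207.5, 282.0 and 340.0 in Con and 468.7, 583.4 and 502.1 in Tg (log2 1.17, 0.93 and 0.73, SE 0.24, adjusted p = 0.0132, 0.0247 and 0.636). C3, the central complement protein, was 4043, 4305 and 4796 in Con and 7359, 9888 and 8479 in Tg (log2 0.85, 0.97 and 0.89, SE 0.27, adjusted p = 0.133, 0.0321 and 0.516). Csf1r (0.77, 0.60 and 0.60, SE 0.14, adjusted p = 0.00437, 0.0155 and 0.110) and Adgre1, which encodes the macrophage protein F4/80 (0.88, 0.84 and 0.62, SE 0.22, adjusted p = 0.0431, 0.0269 and 0.790), were higher, as was Itgax, an integrin of myeloid cells (3.19, 1.52 and 1.88, SE 0.55, adjusted p = 0.00244, 0.0778 and 0.409). Klhdc7a (1.23, 1.06 and 1.38, SE 0.20, adjusted p = 0.000824, 0.00375 and 0.000176) and Ndnf (1.35, 0.98 and 1.72, SE 0.20, adjusted p = 0.000316, 0.00839 and 6.64e-06) were higher too. Dmd (-1.15, -0.94 and -1.28, SE 0.16, adjusted p = 0.000119, 0.00105 and 7.13e-06), Ctnna3, an alpha catenin of the intercalated disc (-1.04, -1.04 and -0.91, SE 0.22, adjusted p = 0.0148, 0.00980 and 0.122), and Exoc2 (-0.90, -0.42 and -0.78, SE 0.09, adjusted p = 4.18e-07, 0.0135 and 7.13e-06) were lower. Hprt, a gene of purine salvage, was higher (0.58, 0.66 and 0.69, SE 0.18, adjusted p = 0.115, 0.0295 and 0.194). In TAC hearts Csf1r lost its call without Tg-TAC 4 (adjusted p = 0.0573) and Adgre1 without Tg-TAC 1, 3, 4 or 5 or Con-TAC 1, 3 or 5 (0.0506 to 0.0770), and in sham hearts Ctnna3 lost it without Tg-Sham 6 (0.0597).

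One hypothesis was that a change near a single place in the genome could underlie these genes, and chromosome 13, which holds Exoc2, was tested. Of the 62 genes 4 lay there (H1f2, Exoc2, Polr3g and Atp6ap1l) among 640 tested genes (odds ratio 1.69, 95% interval 0.444 to 4.58, Fisher's exact test, two-sided, p = 0.309), so an enrichment was not detectable in this set. Of the 20 chromosomes tested in this way the smallest p was 0.104, for chromosome 1 (7 of 998 tested genes, adjusted p = 1 over the 20 Fisher tests). Of the 11 genes called with the label in both sham and MitoQ hearts 3 lay on chromosome 13 (Ssbp2, Exoc2 and Polr3g, each lower in Tg) where 0.433 are expected (odds ratio 9.20, 95% interval 1.57 to 38.4, Fisher's exact test, two-sided, p = 0.00788, adjusted p = 0.158 over the 20 chromosomes). Polr3g was not called in sham hearts without Tg-Sham 6 (adjusted p = 0.0519). This set was tested because these genes had been seen there, so the hypothesis stays open. Polr3g, Atp6ap1l and Ssbp2 lie between 81821962 and 91851548 on that chromosome, and Exoc2 between 30997902 and 31158076.

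Further lists were tested for TAC in Tg hearts, with adjusted p = 0.411 with an estimated correlation unless given. Of 20 fetal and hypertrophy genes 8 rose and 1 fell, 9 and 1 adjusted over the list alone (camera adjusted p = 0.000425). Of 22 cell cycle genes 3 rose and 1 fell, 6 and 1 adjusted over the list alone (median log2 0.79, camera adjusted p = 0.000324). Of 7 Schwann and neuronal markers 5 fell, 6 adjusted over the list alone (median log2 -1.29, camera adjusted p = 0.000324). All 19 interferon-stimulated genes had a positive difference with none called (median log2 0.60, camera adjusted p = 0.00115, 0.459 with an estimated correlation). The next 2 lists did not pass. Of 23 glucose uptake and glycolysis genes 9 rose and 6 fell, 11 and 7 adjusted over the list alone (camera adjusted p = 0.10, 0.412 with an estimated correlation). Of 18 circadian clock genes 3 fell, 5 adjusted over the list alone (camera adjusted p = 0.175, 0.459 with an estimated correlation). Of the 7 sirtuins 2 were higher in Tg-TAC than in Con-TAC (camera adjusted p = 0.526), and limma called none of the 7 with TAC in either genotype or with the label in sham hearts.

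Single libraries held values of their own. Adipoq was 2678 in Tg-TAC 4, and Myl7, an atrial myosin light chain, was 4611 in Con-TAC-MQ 5. Con-Sham 2 had 31.2% of the listed genes at 0.

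The libraries of each comparison were also split in 100 ways, the real one included. Fewer than 5 of 100 splits gave as many genes in 6 comparisons. These were TAC in Con (863 genes, highest other split 28), TAC in Tg (2716 and 1649), the label in sham hearts (142 and 0), MitoQ in Tg (2821 and 2725), MitoQ in Con (526 and 1866) and the label in MitoQ hearts (12 and 41). The real split was the only one of 100 with as many genes in the first 4, which argues against chance at 5% for each taken alone. In the last 2, 3 of 100 splits gave as many. The splits are a sample of those possible, so a rate this near 5% does not settle whether chance gave these 2 counts. Chance cannot be excluded for the label in TAC hearts, where 7 of 100 splits gave as many genes (1054 and 4355). For the interactions the real count was 0 in limma, which all 100 draws of permuted residuals reach by construction, so they say nothing about chance (highest other 57 for TAC and 1 for MitoQ). A split that calls several times the real count, as for the label in TAC and in MitoQ hearts and for MitoQ in Con, points to a structure of the samples other than the comparison. In TAC hearts that split set Tg-TAC 1, 3, 4 and 5 with Con-TAC 4 and 6 against the rest. In Con hearts the split with 1866 genes set Con-TAC 1 to 5 with Con-TAC-MQ 4 against Con-TAC 6 with the other MitoQ libraries, and the one with 2725 genes in Tg hearts set Tg-TAC 1 to 5 with Tg-TAC-MQ 1 against the rest, which follows the class of the name number as far as 6 against 6 allows. With the class of the name number in the model MitoQ in Con gave 225 genes and MitoQ in Tg 2551, both resting on Con-TAC 6 for the shift of the MitoQ libraries.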
